A study of Mus musculus with 2 samples.

How the data were processed

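The study sequenced messenger RNA of mouse mammary basal cells in 2 libraries, 1 with a scrambled hairpin and 1 with a Cdk14 hairpin. Per the labels' protocols, libraries were made from total RNA with a stranded mRNA kit. The labels disagree on the material: the title and sample labels name mouse mammary basal cells, the design text names MDA-MB-231, a human breast cancer cell line, and the extraction protocol names retinas. The identifiers in the table are mouse Ensembl genes, and the sample labels were followed. Per the submitters' processing notes, the tools were Bowtie 0.12.2 and featureCounts from Subread 1.5.1, and the builds mm8 and GRCm38 are named without a role. How multiply mapped or overlapping reads were treated, which bears on genes with near-identical copies, and whether counting used strand, is not given in the sources used here.

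The authors deposited 1 table of FPKM values, which scale the fragments of a gene to its length and to the library's total, with a column for each library. The column names abbreviate the sample titles, and each was assigned to the only title it fits. The table lists 15239 genes and none at 0 in either library, so genes found in one library alone are absent from every comparison, and counts of genes with large differences leave them out. The reads behind the values were recovered with exonic lengths from GENCODE M21 (GRCm38). For 79.1% of the 15195 genes with a length, the product of value and length was a multiple of 0.5 reads in both libraries (tolerance 0.01 reads). Among the 3169 other genes, 11.3% of Scramble control values and 12.4% of Cdk14-sh values were at a fraction of 0.17, 0.33, 0.67 or 0.83 of a read, where 1.60% would be by chance. Annotated lengths can differ from the authors' for the rest, whose read numbers and intervals are approximate. The values correspond to totals of 10186924 and 10177185 reads, a ratio of 1.00, so the totals used for scaling were nearly equal in the libraries. These totals take the smallest step as 0.5 reads, which the fractions above fit; the ratio of the totals does not depend on that choice. Recovered reads over all genes with a length came to 112% of each total; the cause of this excess was not tested. Of the whole read numbers, 70.9% in Scramble control and 67.5% in Cdk14-sh were even, against 50% for reads counted singly, and the commonest of the lowest values was 2 reads (631 and 423 genes). For this reason 2 reads were taken as 1 independent fragment in every interval, a choice made after seeing the data. Intervals of a fold are exact 95% binomial (Clopper-Pearson) intervals of the share of fragments from one library, turned into a ratio. They cover counting error only, since reads without molecular identifiers are not independent molecules.

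The groups, the gene lists, the rule for named genes and the measures were fixed before the data were examined. The log2 ratio is log2 of (Cdk14-sh FPKM + 1) over (Scramble control FPKM + 1), which understates the difference of low genes; fold values in the text are ratios of FPKM without a pseudocount. Genes with a mean of at least 1 FPKM over both libraries were measured (12830), and 2-fold differences were counted on the log2 scale. For each of 40 fixed lists and 27 symbol families, the median log2 ratio was set against 10000 random lists of the same size, drawn from 20 bins of mean FPKM. Its percentile describes these 2 libraries, treats genes as independent and is no test. Lists with fewer than 5 measured members got none. Of genes sharing a symbol, the one of highest mean was used. The named genes are Cdk14, the 10 highest and 10 lowest log2 ratios at a mean of at least 5 FPKM without unnamed gene models and pseudogenes, and up to 3 highest and 3 lowest members of each list or family described; the other names are marked as chosen after their values were seen.

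Alternatives were pseudocounts of 0.1 and 5, 4 scalings of the Cdk14-sh values, summed values of shared symbols, no filter or a mean of at least 5 FPKM, limits of 1.5-fold and 4-fold, the mean of a list, unmatched random lists and random lists of protein-coding genes. A correction for exonic length and GC content by running medians over 501 genes was chosen after seeing the data. In data simulated for the comparison of Cdk14-sh with Scramble control, depth and fragments were recovered exactly over 14742 genes. These data were built from whole fragments with the same exonic lengths. Their recovery checks the arithmetic, and not how well those lengths fit the deposited values. Of 8045 simulated genes with a mean of at least 5 FPKM, only a small part was changed, so the shares of changed genes rest on few genes. Of those changed 2-fold, 26% passed the 2-fold limit in the right direction. It was 96% of those changed 3-fold, 100% of those changed 4-fold and, in either direction, 0.943% of unchanged genes. The simulation held counting error alone. Observed log2 ratios scattered more, with an SD of 1.08 against 0.30 from counting at a mean of 5 to 10 FPKM. The simulated share of unchanged genes is therefore no rate of false 2-fold differences in the deposited values. After ratios were shuffled within bins, 1 of 36 lists left the central 95%. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.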

Results

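Messenger RNA was sequenced from mouse mammary basal cells that carried either a scrambled short hairpin RNA (Scramble control) or a hairpin against Cdk14 (Cdk14-sh). Mammary basal cells form the outer layer of the gland's epithelium and include the contractile myoepithelial cells. Cdk14 is a cyclin-dependent kinase that acts with cyclin Y at the membrane and promotes Wnt receptor phosphorylation. Each group held 1 library, so no difference has a replicate check, no test was made and no p-value is given. The table listed 15239 genes, each above 0 in both libraries. The FPKM values corresponded to totals of 10186924 reads for Scramble control and 10177185 reads for Cdk14-sh. Intervals in parentheses are 95% intervals for counting error alone. They compare these 2 libraries, not the 2 conditions.

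The comparison asked which transcripts differed when Cdk14 was targeted. Cdk14 itself was lower in the Cdk14-sh library, at 0.713 FPKM against 2.06 FPKM in Scramble control. That is 34.5% of the control level (26.1 to 46.1), from 137 and 397 reads. The gene (ENSMUSG00000028926) is protein coding and lies on the minus strand of chromosome 5 from 4803391 to 5420312 (GRCm38). Its partner cyclin Y (Ccny) was at 12.1 FPKM against 7.36, 1.65-fold higher (1.40 to 1.95). The related cyclin Ccnyl1 was 11.2-fold lower (7.42 to 17.6), at 1.42 FPKM against 15.9. Among the 9 measured genes of the Cdk14 axis (Cdk14, its cyclins and related kinases), the median log2 ratio was 0.04 and 5 were above 0. Ccnd3, a D-type cyclin, was 3.87-fold higher (3.09 to 4.88), Cdk17 was 1.61-fold higher (1.41 to 1.83) and Cdk5 was at 6.98 FPKM against 7.61. With a pseudocount of 1 the log2 ratio of Cdk14 was -0.84, and 102 of the 500 genes nearest to it in mean FPKM had a ratio as low or lower. The difference in Cdk14 was thus beyond its counting error but within the gene-to-gene scatter at its abundance, where the SD of log2 ratios was 0.98.

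Among 12830 genes with a mean of at least 1 FPKM, 1828 were at least 2-fold higher in Cdk14-sh and 1735 were at least 2-fold lower, together 27.8%. The highest ratios belonged to Serpinb11, Penk, Ctss, Ly6d, Sap30, Car2, Lgals7, Pmaip1, Mir132 and Snrpn, and the lowest to Ltf, Ctla2a, Actg2, Gpihbp1, Adamts4, Slpi, Plvap, Mir7678, Adgrl4 and Snupn. Serpinb11, a clade B serpin on chromosome 1 (107361198 to 107380475), stood at 79.7 FPKM against 0.0898, or 1773 reads against 2, a ratio of 887 (159 to 35107). Penk encodes the opioid precursor proenkephalin and was 246-fold higher (67.9 to 2043), at 59.2 FPKM. Ly6d, a surface marker of luminal and stratified epithelial cells, was 31.5-fold higher (18.9 to 56.7), at 125 FPKM against 3.96. The carbonic anhydrase gene Car2 was at 25.2 FPKM against 0.0811, with a ratio of 310.3 (55.3 to 12295). The lysosomal protease gene Ctss was at 26.5 FPKM against 0.145, a ratio of 183 (32.5 to 7274), and the proapoptotic gene Pmaip1 (Noxa) at 22.5 against 0.0742, a ratio of 303 (55.8 to 12414). Ltf, which encodes the iron-binding milk protein lactoferrin and lies on chromosome 9 (111019271 to 111042767), was 187-fold lower (98.3 to 410), at 0.512 FPKM against 95.9. The protease inhibitor Slpi was 16.9 to 23.9-fold lower by its counting interval, at 23.0 FPKM against 460. Adamts4, an aggrecan-cleaving protease, was 23.9-fold lower (20.3 to 28.5), at 5.98 FPKM against 143. Gpihbp1, which carries lipoprotein lipase across capillary endothelium, was 111-fold lower (37.5 to 539), and the endothelial adhesion receptor Adgrl4 was 88.3-fold lower (37.6 to 273). Mir7678 lies within the bounds of Slpi, and 27.3% of the exonic bases of Snrpn and 16.3% of those of Ctla2a are shared with other genes on their strand, so these 3 are uncertain. Mir132, a microRNA gene of 66 bases, had 31 reads against 1 (interval of the ratio 2.49 to 672) and is uncertain as well. Genes such as Sap30 (386 reads against 2) and Snupn (2 against 226) were near the lowest read numbers in one library, and their ratios have wide intervals, 34.3 to 7669 for Sap30 and 19.9 to 4498 for Snupn.

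**Figure D1:**
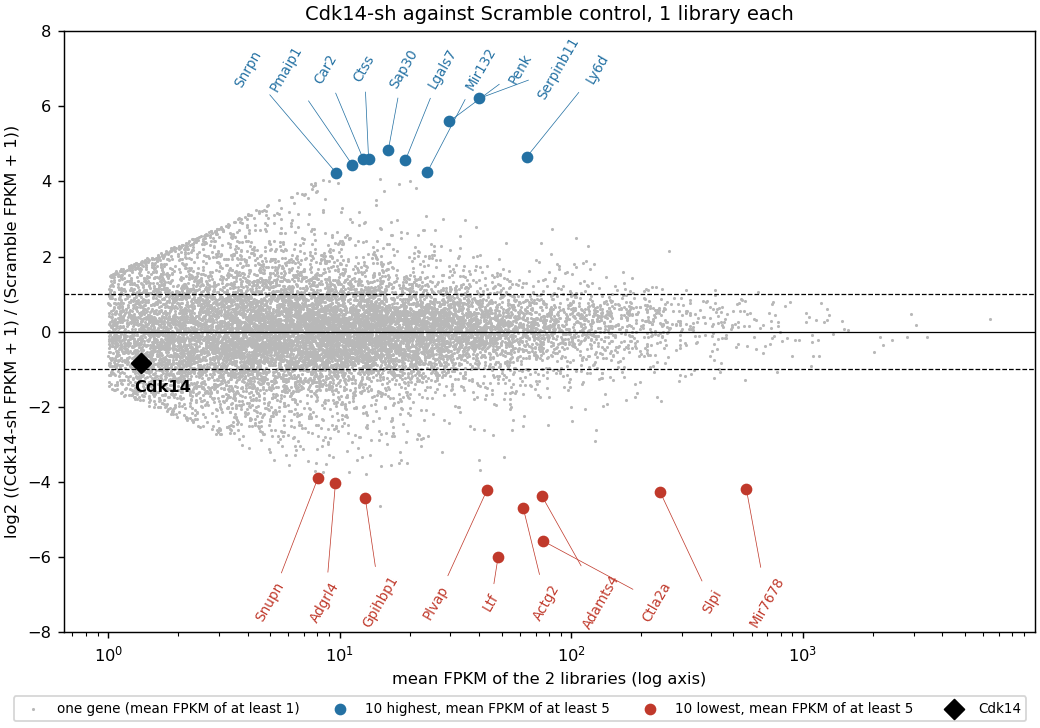
Each grey point is 1 of 12830 genes, with the mean FPKM of the 2 libraries on a log axis and the log2 ratio of Cdk14-sh over Scramble control (pseudocount 1) on the vertical axis; dashed lines mark 2-fold. The 10 highest and 10 lowest named genes with a mean of at least 5 FPKM are coloured, and Cdk14 at -0.84 lies inside the cloud of genes of its abundance.

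Basal and myoepithelial markers went in both directions. The median log2 ratio of the 30 measured markers was -0.21, at percentile 1.39 of random lists matched on mean FPKM, and 7 were at least 2-fold lower and 3 at least 2-fold higher. At the low end stood contractile genes. Smooth muscle gamma actin (Actg2) was 32.9-fold lower (22.7 to 49.3), at 3.66 FPKM against 120. Calponin (Cnn1) was 3.37-fold lower (3.18 to 3.57), and transgelin (Tagln) was 2.80-fold lower (2.52 to 3.11). The highest were Lgals7, an epithelial galectin, 59.4-fold higher (20 to 291) at 37.7 FPKM, Igfbp2, an insulin-like growth factor binding protein, 3.56-fold higher (3.23 to 3.94), and Trp63, the transcription factor that maintains basal identity, 2.83-fold higher (2.51 to 3.21) at 23.9 FPKM against 8.42. Further markers, named after their values were seen, were the smooth muscle genes Myh11 (46.6 FPKM against 104) and Acta2 (696 against 1095) and the basal keratin genes Krt5 (242 against 129), Krt15 (192 against 108) and Krt14 (994 against 1199). The list's place outside the central 95% was lost with unmatched random lists and with the mean in place of the median. In Tagln, 67.9% of exonic bases are shared with genes on the opposite strand, and whether the counting used strand is not given in the sources used here.

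Luminal markers were also lower as a list, with a median of -0.35 over 24 measured genes at percentile 1.31. Of these, 8 were at least 2-fold lower, including Ltf, the tetraspanin gene Tspan8 (36.5-fold, 13.6 to 200) and the transferrin gene Trf (3.98-fold, 3.70 to 4.28; 63.5% of its exonic bases are shared with another gene on its strand). On the other side, 4 were at least 2-fold higher, including Ly6d, the progenitor marker Prom1 (6.15 FPKM against 0.0684, a ratio of 89.9 with an interval of 30.8 to 936) and Wfdc18 (2.79-fold, 2.30 to 3.42). The keratin family had a median of 0.26 at percentile 75.5, and was above the central 95% (percentile 98.0) with a mean of at least 5 FPKM. Its highest members were Krt79, 16.0-fold higher (11.6 to 22.4) at 26.9 FPKM against 1.69, and Krt10, 4.48-fold higher. The luminal keratin Krt19 came next, 2.09-fold higher (1.76 to 2.49). At the family's low end, the simple-epithelial keratin Krt18 was 3.62-fold lower (3.34 to 3.92) at 106 FPKM and Krt42 3.40-fold lower (2.15 to 5.54). Krt8, the partner of Krt18, was 2.05-fold lower (1.95 to 2.16) at 223 FPKM. Squamous differentiation genes lay above the central 95% (median 0.81, percentile 99.6, 12 measured). Their highest members were the secreted epidermal protein gene Dmkn (5.22-fold higher, 3.96 to 6.98), the suprabasal keratin Krt10 (4.48-fold, 2.82 to 7.51) and Lypd3 (3.24-fold, 2.92 to 3.60), whereas Slpi, given above at 23.0 FPKM against 460, was its lowest member and Krt1 was 2.90-fold lower (1.66 to 5.24). This list was within the central 95% with a pseudocount of 5 and with the mean, and the luminal list without a filter on low values and with unmatched random lists. Only 3 of 12 milk genes were measured: casein Csn3 was at 45.6 FPKM against 47.1, Xdh was 3.10-fold lower (2.14 to 4.60) and the lipid droplet gene Plin2 was 1.64-fold higher (1.5 to 1.8).

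Markers of other cell types of the gland moved in different directions. Endothelial markers had the lowest median of the 36 fixed lists that could be ranked (-1.60, percentile 0, 13 measured), with 9 at least 2-fold lower and none at least 2-fold higher. Plvap, the diaphragm protein of fenestrated capillaries, was 23.3-fold lower (16.7 to 33.5), at 3.56 FPKM against 83.0. Endomucin (Emcn) was 108-fold lower (41.8 to 398), and Pecam1, the endothelial junction protein CD31, was 8.63-fold lower (6.62 to 11.4), while the endothelial secreted factor Egfl7 (3.10 FPKM against 2.80) and the coreceptor Eng (8.97 against 9.29) were within counting error of each other. Of 10 measured fibroblast markers, 4 were at least 2-fold lower, including decorin (Dcn, 2.53-fold, 2.37 to 2.71) and gelsolin (Gsn, 4.23-fold, 3.89 to 4.60), and 3 at least 2-fold higher, including Fbln1 (6.86-fold, 4.74 to 10.2) and Col1a2 (2.71-fold, 2.30 to 3.19). The fibroblast median of -0.75 (percentile 0.920) turned to 1.02 at a mean of at least 5 FPKM, so this list has no stable direction. Immune cell markers were higher, with a median of 1.82 at percentile 100 and 7 of 9 measured genes at least 2-fold higher. Examples were the MHC class II genes H2-Aa (9.22-fold, 7.56 to 11.4) and H2-Ab1 (5.28-fold, 4.67 to 5.98), at 50.2 and 125 FPKM, and the macrophage receptor gene Csf1r (4.05-fold, 2.68 to 6.14). The leukocyte gene Coro1a was 2.46-fold lower (1.32 to 4.83). At a mean of at least 5 FPKM too few immune markers were left for a percentile. The pericyte genes Mcam (5.50-fold, 3.85 to 7.85), Abcc9 (3.57-fold, 2.33 to 5.64) and Rgs5 (2.06-fold, 1.93 to 2.21) were lower. The remaining measured pericyte marker, the muscle filament gene Des, was higher, at 2.41 FPKM against 0.0523, a ratio of 46.0 (7.86 to 1858). Of 12 adipocyte markers only Fabp4 was measured, and it was 11.2-fold lower (9.63 to 13). Of 24 retina genes, 5 were in the table and 3 were measured: Gnb1, which many tissues express, at 121 FPKM against 127, and the photoreceptor genes Gnat1 at 0.130 against 1.88 and Opn1sw at 1.65 against 1.59.

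**Figure D2:**
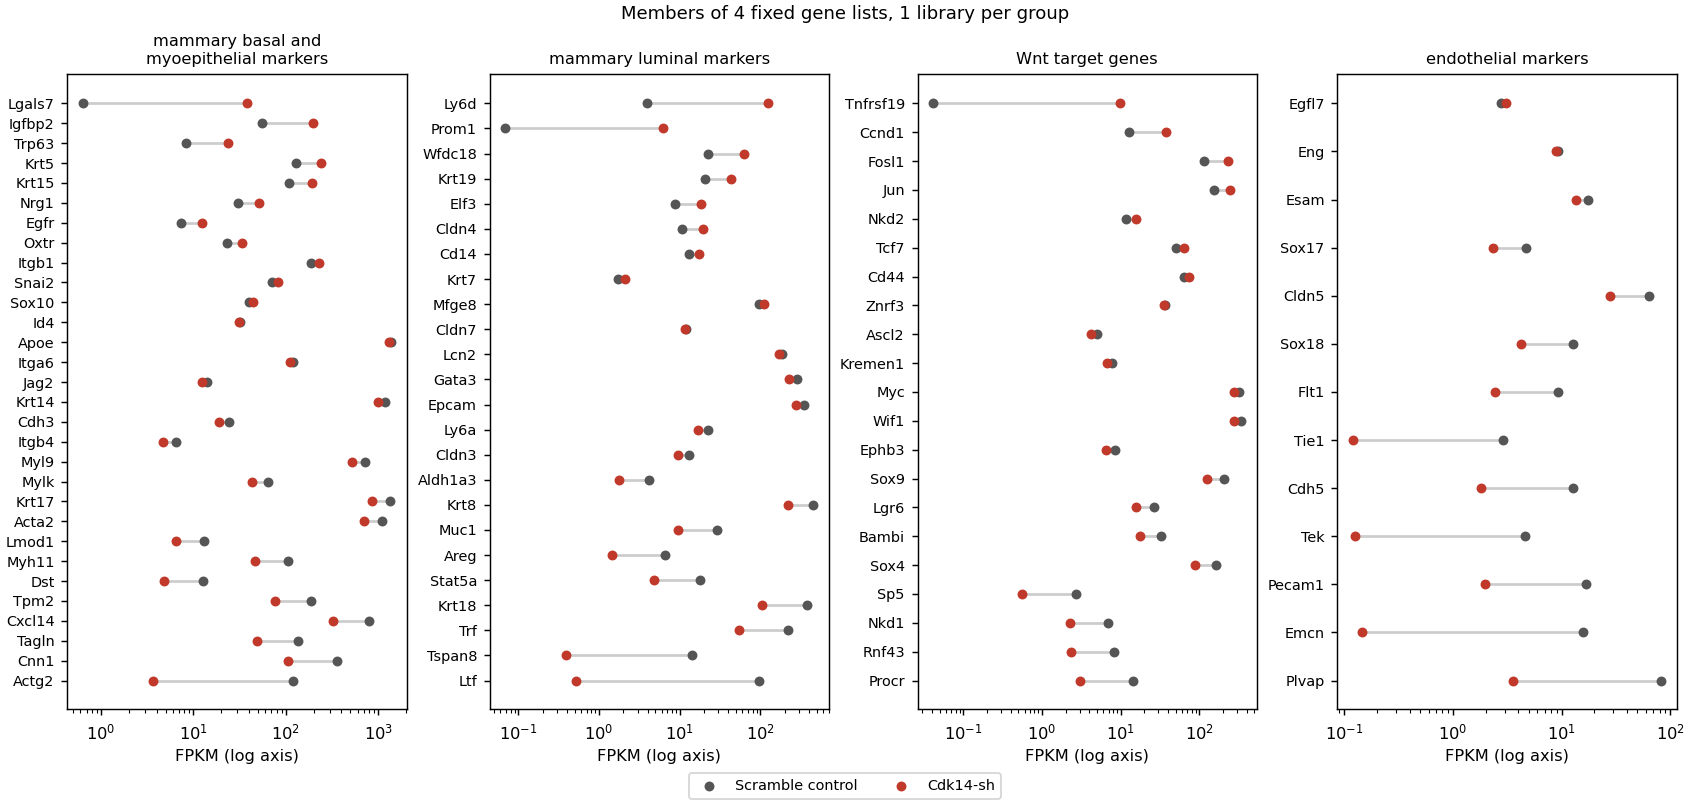
FPKM on a log axis of each measured member of 4 fixed lists in Scramble control (grey) and Cdk14-sh (red), 1 library each, ordered by log2 ratio. Contractile genes such as Actg2 and Cnn1 sit at the bottom of the basal panel with Trp63 near the top, and 12 of 13 endothelial markers lie lower in Cdk14-sh.

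Because Cdk14 acts on the Wnt coreceptor, Wnt genes were compared as lists of their own. Transcriptional targets of Wnt signalling had a median log2 ratio of -0.21 over 21 measured genes at percentile 6.54, and 14 of them were below 0. At the low end were Procr, a marker of mammary stem cells (4.66-fold lower, 3.11 to 6.95), and the feedback inhibitors Rnf43 (3.56-fold, 2.74 to 4.61) and Nkd1 (3.07-fold, 2.24 to 4.29). At the high end were Tnfrsf19 (9.65 FPKM against 0.0411, a ratio of 235 with an interval of 41.5 to 9251), cyclin D1 (Ccnd1, 2.95-fold, 2.59 to 3.37) and the AP-1 member Fosl1 (1.98-fold, 1.85 to 2.13; 57.2% of exonic bases shared with a gene on the opposite strand). The pathway's components had a median of 0.02 over 37 genes, with 5 at least 2-fold higher and 5 at least 2-fold lower. The receptor Fzd8 was 12.5-fold lower (5.92 to 32.5) and the antagonist Sfrp2 3.05-fold lower (2.29 to 4.08), while the receptor Fzd6 was 9.76-fold higher (5.6 to 18.3) and the transducer Dvl1 5.69-fold higher (3.96 to 8.40). Neither of these lists left the central 95% under any of the 13 alternative settings. The family of Wnt ligands (7 measured) had a median of -0.73 at percentile 3.29, and was below the central 95% with a pseudocount of 5 (0.620) and after the correction for exonic length and GC content (1.73). It was at percentile 24.4 without a filter on low values, and had too few genes for a percentile at a mean of at least 5 FPKM. Its lowest member was Wnt16, at 0.0451 FPKM against 2.70, 59.9-fold lower (10.4 to 2407) from 2 recovered reads in Cdk14-sh, and its highest Wnt11, 2.03-fold higher (1.52 to 2.72).

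Cyclins were the only symbol family above the central 95% (median 0.76 over 14 genes, percentile 99.6), with 7 at least 2-fold higher. At a mean of at least 5 FPKM the family was just within it (percentile 97.4). The family holds only symbols with a digit right after the cyclin letter, so Ccny and the lower Ccnyl1 are not in it. Ccnd2, a D-type cyclin of G1, was 3.22-fold higher (3.07 to 3.39) at 135 FPKM, with Ccnd1 and Ccnd3 as above, and the S and G2 cyclin Ccna2 was at 3.07 FPKM against 0.0721, a ratio of 42.5 (11.1 to 2569). The G1 cyclin Ccne1 was 19.2-fold lower (7.21 to 72.4). G1/S genes had a median of 0.35 at percentile 97.4, within the central 95% by a small margin. Alternative settings moved this percentile both ways: 5 put it above the central 95%, and at a mean of at least 5 FPKM it fell to 47.1. G2/M genes had a median of 0.28 at percentile 87.8, above the central 95% without a filter on low values and with the mean. The replication helicase genes Mcm5 (6.10 FPKM against 0.0492) and Mcm6 (5.14 against 0.0421) and the mitotic genes Ccnb1 (7.43 against 0.0466), Ect2 (5.22 against 0.0365) and Tacc3 (7.33 against 0.0276) were near the lowest read numbers in Scramble control, with ratios from 122 (21.5 to 4862) for Mcm6 to 265 (23.5 to 5297) for Tacc3. The mitotic genes Gas2l3 (14.1-fold, 8.85 to 23.2) and Ckap5 (1.99-fold, 1.73 to 2.29) were lower in Cdk14-sh.

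NF-kB and cytokine genes, TGF-beta targets, integrin and focal adhesion genes and immediate early genes had medians below the central 95%. NF-kB and cytokine genes had a median of -0.64 over 22 genes (percentile 0.0300), with 18 below 0 and 9 at least 2-fold lower. The monocyte chemoattractant Ccl2 was 6.26-fold lower (5.39 to 7.30), at 35.1 FPKM against 220, Tnfaip2 was 4.51-fold lower (3.61 to 5.68) and the leukocyte adhesion receptor Vcam1 3.64-fold lower (3.25 to 4.08), whereas prostaglandin synthase Ptgs2 was 5.36-fold higher (4.53 to 6.43). TGF-beta target genes had a median of -0.50 (percentile 0.220), with 16 of 21 below 0, among them Tagln (values above), the corepressor gene Tgif1 (2.26-fold lower, 2.13 to 2.39) and the matrix gene Tgfbi (2.5-fold, 1.75 to 3.70). The latent TGF-beta binding protein Ltbp2 was 3.35-fold higher (2.91 to 3.89). Integrin and focal adhesion genes had a median of -0.39 (percentile 1.03), with 20 of 27 below 0, led by Itga1 (2.46-fold lower, 2.18 to 2.79), the actin crosslinker Actn1 (2.25-fold, 1.96 to 2.59) and Tns1 (2.20-fold, 1.92 to 2.52), while the kinase Src was 3.94-fold higher (2.82 to 5.59). Immediate early genes, which respond within minutes to stimuli, had a median of -0.19 (percentile 1.37) and were mixed, with 16 of 26 below 0, 4 at least 2-fold lower and 2 at least 2-fold higher. Egr2 was 3.16-fold lower (2.84 to 3.51), Socs3 3.10-fold lower (2.91 to 3.29) and Fos 2.09-fold lower (2.01 to 2.18), with Dusp5 2.47-fold higher (2.31 to 2.64). The TGF-beta, integrin and immediate early lists were within the central 95% when the mean replaced the median, and the last also with unmatched random lists.

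Ribosomal protein genes were higher, and nuclear genes of the respiratory chain were higher as a list with members on both sides. All 57 ribosomal protein genes had a log2 ratio above 0, with a median of 0.61 (percentile 100, random lists -0.04 to 0.36), though only 4 were at least 2-fold higher. They ranged from Rps2, at 191 FPKM against 178, to Rpl22, 2.32-fold higher (2.03 to 2.66). Rpsa was 2.23-fold higher (2.06 to 2.41) and Rps12 2.22-fold higher (2.09 to 2.36); genes of this class have many processed pseudogenes that can share their reads. Nuclear genes of the respiratory chain had a median of 0.38 (percentile 99.3), with 34 of 45 above 0, such as the complex I gene Ndufa9 (2.42-fold, 1.98 to 2.99) and the cytochrome oxidase gene Cox5a (2.37-fold, 2.0 to 2.83). Only 3 were at least 2-fold higher, and 11 were below 0, among them the complex I gene Ndufs1 (1.86-fold lower, 1.62 to 2.14) and Ndufa4 (1.46-fold lower, 1.35 to 1.58). Cholesterol synthesis genes had a median of 0.50 (percentile 98.0), with 7 of 19 at least 2-fold higher, including Dhcr7, which catalyses the last step of cholesterol synthesis (16.0-fold, 8.49 to 34.0), and Acat2 1.61-fold lower (1.43 to 1.82). The cholesterol list was within the central 95% under 5 other settings, and the respiratory chain list (percentile 96.7) after a correction for exonic length and GC content.

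**Figure D3:**
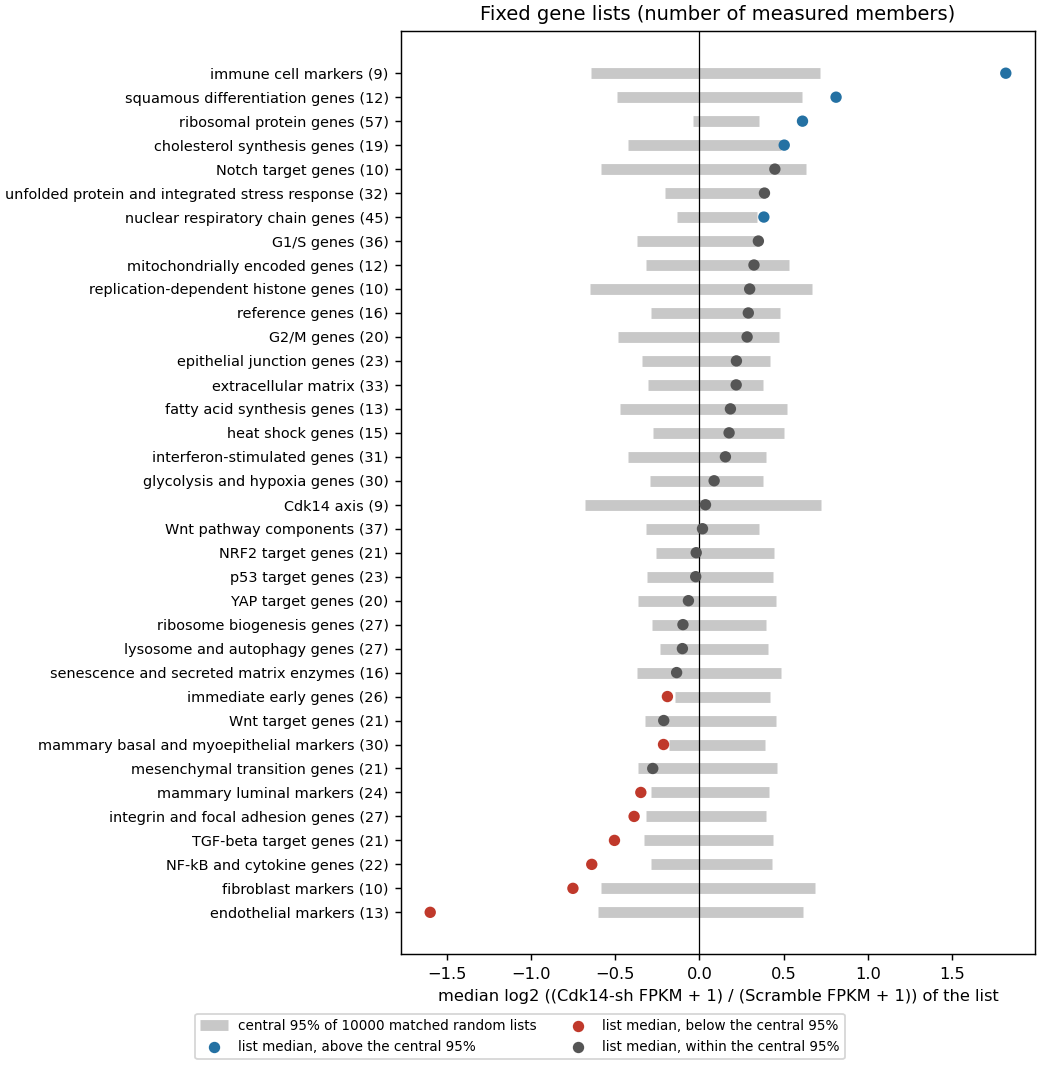
Median log2 ratio of each of the 36 fixed lists with at least 5 measured members (points) and the central 95% of 10000 random lists matched on mean FPKM (grey bars). In all, 5 lists lie above their bar and 8 below it, with endothelial markers at -1.60 and immune cell markers at 1.82 farthest out.

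The other ranked lists were within the central 95% in the main setting. Genes of the unfolded protein and integrated stress response (median 0.39, percentile 97.4) were above it under 8 of the 13 alternative settings, with percentiles from 93.3 to 99.4, with the endoplasmic reticulum chaperone Hsp90b1 3.04-fold higher (2.88 to 3.22) at 252 FPKM. Interferon-stimulated genes (0.15) held Rsad2 at 14.9 FPKM against 0.0454, a ratio of 329 (58.9 to 13086), and the RNA sensor kinase Eif2ak2 18.4-fold lower (10.8 to 32.8). Mesenchymal transition genes (-0.28) held the receptor kinase Axl 4.34-fold lower (3.94 to 4.78) and fibronectin (Fn1) 8.53-fold higher (6.29 to 12.1). Notch targets (0.45) held Hes1 2.73-fold higher (2.54 to 2.94), at 266 FPKM, and p53 targets (-0.02) held Trp53inp1 3.44-fold lower (2.97 to 4.0) and Sesn2 7.05-fold higher (5.15 to 9.86). Among senescence-associated secreted genes (-0.14, and below the central 95% at percentile 1.12 with a mean of at least 5 FPKM), Igfbp5 was 4.47-fold higher (4.30 to 4.66) at 432 FPKM and the protease inhibitor Timp1 8.69-fold lower (5.46 to 14.6). Medians were 0.22 for epithelial junction genes, 0.22 for extracellular matrix genes, -0.07 for YAP targets, 0.18 for heat shock genes, -0.02 for NRF2 targets and 0.18 for fatty acid synthesis genes. They were 0.09 for glycolysis and hypoxia genes, 0.32 for mitochondrially encoded genes, -0.10 for ribosome biogenesis genes, 0.30 for replication-dependent histone genes, -0.10 for lysosome and autophagy genes and 0.29 for reference genes. Some genes of general use had very low values: Gapdh was at 2.20 FPKM against 0.333, and mt-Co3 at 1.00 in both libraries beside mt-Co1 at 1584 against 1541. The cause was not tested, so a low FPKM in this table does not show by itself that a transcript was scarce. Of the 36 ranked lists, 13 lay outside the central 95%, where 1.80 would be for random lists that are independent. The fixed lists share some members, such as Tagln in the basal and TGF-beta lists, so the 13 are not separate observations.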

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

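Cdk14 was lower in the Cdk14-sh library under each setting tried. Its log2 ratio of -0.84 became -1.41 with a pseudocount of 0.1, -0.31 with a pseudocount of 5 and -0.65 after the correction for exonic length and GC content, which was chosen after seeing the data. The 3563 genes at least 2-fold apart, of which 1828 were genes at least 2-fold higher in Cdk14-sh and 1735 were genes at least 2-fold lower in Cdk14-sh, became 1289 (677 and 612) with a pseudocount of 5, which shrinks ratios, and 1855 (946 and 909) at a mean of at least 5 FPKM, where fewer genes are counted. They became 6380 (3239 and 3141) at a 1.5-fold limit and 764 (419 and 345) at a 4-fold limit, as a lower or higher limit must give. The share of higher genes at the 2-fold limit, 51.3%, lay between 47.1% and 52.8% under the alternatives that kept this limit. No scaling moved ratios by more than 0.07 on the log2 scale. Of the 13 fixed lists outside the central 95%, the endothelial, NF-kB and cytokine, and ribosomal protein lists were outside under all 13 alternative settings, 3 in all. The fibroblast median of -0.75 reversed to 1.02 at a mean of at least 5 FPKM; this filter leaves fewer markers. No paired analysis was possible because each group held 1 library, and no library could be left out. Depth limits genes with few reads: at a mean of 1 to 2 FPKM, counting alone would give an SD of log2 ratios of 0.40, against 0.96 observed.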

Other observations

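The symbol families were fixed before the data were examined. The tests of the explanations for Cdk14, the ribosomal protein genes and the endothelial markers were chosen after the main values had been seen, each with its bounds written before its own result, except that the measure deciding between scatter and an endothelial difference was settled afterwards.

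Of 24 ranked symbol families, 4 lay outside the central 95% of matched random lists, where 1.20 would be for independent random lists: cyclins above, and serpins, ADAMTS proteases and Sox genes below. Serpins had a median log2 ratio of -0.98 over 16 genes (percentile 0), with the acute-phase serpin Serpina3n 6.15-fold lower in Cdk14-sh (5.02 to 7.63) and Serpina3h, annotated as a transcribed pseudogene, 4.88-fold lower (4.09 to 5.82). Both belong to a multigene family, so their values are uncertain where counting split shared reads, which was not tested. Serpinf1, the angiogenesis inhibitor PEDF, was 2.47-fold higher (2.17 to 2.81) and Serpine2 2.11-fold higher (1.98 to 2.26). ADAMTS proteases had a median of -0.78 over 12 genes (percentile 1.09), with Adamts4 lowest, Adamts20 56.6-fold lower (19.0 to 277) and Adamts9 4.13-fold lower (3.58 to 4.78), while Adamts18, expressed in mammary myoepithelium, was 5.86-fold higher (4.79 to 7.23). Sox genes had a median of -0.76 over 8 genes (percentile 1.12): Sox8 was 4.08-fold lower (2.39 to 7.21), the endothelial factor Sox18 2.98-fold lower (2.01 to 4.49) and Sox9 at 126 FPKM against 207, while Sox15 was 14.2-fold higher (2.84 to 751), at 4.05 FPKM against 0.285, and the neural crest and mammary progenitor factor Sox10 was at 44.3 FPKM against 39.7. The ADAMTS family was within the central 95% with a pseudocount of 5 and without a filter on low values, and had too few members for a percentile at a mean of at least 5 FPKM. Within it too were the Sox genes without a filter on low values and with the mean of the family, and the serpins with the mean.

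A group of genes was near its lowest possible value in one library and well covered in the other. With at most 4 reads in one and at least 100 in the other, 164 genes were low in Scramble control and 48 in Cdk14-sh. Of the G1/S and G2/M lists, 3 genes each were low in Scramble control and 0 in Cdk14-sh. At a mean of at least 100 FPKM the SD of log2 ratios was 0.75, where counting alone would give 0.07.

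The decrease of Cdk14 could reflect the hairpin or the general scatter between the 2 libraries. Counting error is argued against, since the upper end of the 95% interval of its read ratio was 0.461. Scatter remains open: Cdk14 was at percentile 20.4 of the 500 genes nearest in mean FPKM, so a ratio as low was common among genes no hairpin was aimed at. A second Cdk14-sh library would be needed to separate them.

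The higher ribosomal protein transcripts may be technical or biological. After removal of a trend with exonic length and GC content, their median was 0.47, at percentile 100. This result could hardly have differed, because the trend was small. Over groups of genes ranked by exonic length, median log2 ratios ran from -0.12 to 0.15. By GC content they ran from -0.10 to 0.10. The trend over all genes was thus too small to account for the ribosomal median of 0.61, and the percentile adds no further evidence. The test of scaling was void, because its 4 factors moved all genes alike by at most 0.07 on the log2 scale, too little to bring the median (0.54 at its lowest) to the bound of 0.1. Reads shared with processed pseudogenes, the state of the cells and the hairpin itself stay open, the last untested with 1 library per group.

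Endothelial transcripts may have made up less of the Cdk14-sh library, as a hypothesis about cells accompanying the basal cells; a sort for basal cells, if used, is not described in the labels. A second list of 30 endothelial genes, none in any fixed list, had 26 measured and a median at percentile 0; its most abundant genes were Tm4sf1 (219 FPKM against 263), which other cells also express, Cd36 (28.9 against 223) and Ly6c1 (22.0 against 86.2). Scatter among unrelated genes is argued against by that list's median of -0.81, below the -0.38 that bounds random lists. That median is the value behind the percentile of 0, not separate evidence. Random lists treat genes as independent, so scatter shared by genes that vary together is not covered. The share of the list's genes above 0 (6 of 26, 23.1%) was too close to the bound of 25% to decide. A lower share of all accompanying cells was set against a second list of antigen-presenting cell genes, with 9 of 35 measured. Its median was 0.94 (percentile 99.0), above the bound of 0, but this argues only weakly against that explanation. Of the 9, 4 were below 0, among them Ifi30 (35.6 FPKM against 84.8). Cybb and Cd53, among the higher ones, were at 0.0338 and 0.0564 FPKM in Scramble control, near the lowest values. The fixed immune list was at 1.82, with too few genes for a percentile at a mean of at least 5 FPKM. Other markers fell with the endothelial ones: 3 of 4 measured pericyte markers were at least 2-fold lower, and Fabp4 was 11.2-fold lower. The remaining pericyte marker, Des, was higher, at 2.41 FPKM against 0.0523 in Scramble control. Fabp4 was the only adipocyte marker measured of 12, so it cannot speak for adipocytes. The fibroblast list was at percentile 0.920, though at 99.7 with a mean of at least 5 FPKM. A lower share of several accompanying cell types thus stays open, and the immune lists do not settle whether immune cells were spared. An effect of the hairpin on these genes in basal cells stays open and untested.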
